A study of Rattus norvegicus with 4 samples.

How the data were processed

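Gene expression was measured by microarray in fibroblasts taken from rat tail tendons (Lewis rats, retired breeders) and cultured inside gels of type I collagen. Per the labels' protocols, the cells grew for 2 days in a medium with 10% fetal bovine serum and were then moved to a medium without that serum that held 10% of the releasate of a clotted plasma product, either PRP or PPP. The labels give only these abbreviations; they are read here, from general usage, as platelet-rich plasma and platelet-poor plasma. The donors of the plasma are not given in the labels, nor whether both products came from the same ones. RNA was taken after 24 hours. Per the labels' protocols, cDNA was amplified from 15 ng of total RNA and 3 ug of cDNA was labelled with biotin for an Affymetrix array. There were 4 arrays, 2 for PRP and 2 for PPP. The labels number the replicates but do not say whether they came from separate animals or cultures. The p-value of a probe set therefore measures only the spread between these arrays, which may be technical.

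The deposited table held 36685 probe sets with a log2 value for each array. Per the submitters' processing notes, oligo, RMA and limma were used, with no version, role or order given. RMA corrects background, makes the distributions of the arrays equal and summarises the probes of a probe set on the log2 scale; the deposited log2 values match that form. They ranged from 0.861 to 12.3, and the sorted values of any 2 arrays differed by at most 0.304. Scanner files were not used here, so no detection call or saturation flag entered the work, and a low value could not be told from background. Folds are ratios of RMA values, and a fold against a low level is uncertain to that extent. Such levels include those of Il1a, Lcn2, Prl6a1, Pf4, Usp18, Mmp10, C3 and Tlr2 with PPP. With PRP they include those of Plekha6, C1qtnf3, Cilp, Tnmd and Kera. The genome build and the annotation version behind the arrays are not given in the sources used here, and no coordinates are printed. RMA makes the overall level of the arrays alike, so a change in the total amount of RNA per cell would not show. Differences are taken between arrays within a probe set. Levels of different probe sets are not comparable, and the count of marker genes above the median of all genes in the closing section is a rough guide to which of them the cultures express.

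Gene names came from the platform's annotation table in GEO. It paired 14824 probe sets with exactly 1 gene symbol and 829 with several, and the other 21032 probe sets are unnamed here. Of the single-symbol probe sets, 14670 had an Entrez identifier that is also in the GRCr8 gene table, and 0 symbols had to be updated. The 14824 probe sets stood for 14557 genes, of which 234 had more than 1 probe set. A gene with several was represented in list tests by the one with the highest mean over the 4 arrays. In 22 cases a named probe set repeated the 4 values of another. Genes with near-identical copies, such as members of the prolactin family, metallothioneins, globins and Mmp3 with Mmp10, can share probes, and their values are uncertain to that extent.

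PRP was compared with PPP by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no intensity trend, two-sided), over the 14824 single-symbol probe sets with no filter on dim ones. A probe set was called at a Benjamini-Hochberg adjusted p below 0.05. The fit had 2 residual degrees of freedom and 3.87 prior degrees of freedom per probe set. Differences are given as log2 PRP minus PPP with limma's moderated standard error (SE), and group levels as mean ± SD of the 2 arrays. With arrays there is no read depth, and the number of arrays limits the precision.

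A set of 21 gene lists was written before the data were examined: 14 of responses and 7 of markers of other cell types the cultures or the plasma could hold. Each was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 21 lists. That test sets genes against genes, so its p rests mainly on the number and spread of genes. A small p of a list is not evidence from replicates. The same test with a correlation estimated from the residuals, which has only the 2 residual degrees of freedom, called 0 lists, and its adjusted p is given beside each called list. Among the called lists the estimated correlation ran from -0.01 (cytokines) to 0.38 (myofibroblast genes). Where it lies above the preset, the preset p may be too small. Members past the threshold were counted over all probe sets tested and, separately, adjusted over the list alone. Alternatives to each choice were also fixed before the data were examined and are reported in the closing section.

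The genes to be named were also set by a rule before the data were examined: the 6 largest rises and 6 largest falls among called genes whose PRP and PPP arrays did not overlap, the 2 members with the smallest p of each response list, and the 1 member with the smallest p of each list of other cell types. Symbols that begin with LOC, RGD, Mir or Olr were passed over. The other genes named below, among them the remaining called members of the lists, were chosen after their values were seen, except the leukocyte transcripts of the closing section, whose set was written down before.

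The fit was tested on simulated data: 20 sets of 14824 independently drawn probe sets with the real means and limma's moderated variances, 200 of them changed. It recovered 24.5% of changes of 0.5 on the log2 scale, 98.8% of changes of 1 and 99.9% of changes of 2, and 7.00% of its calls were false on average. With no change simulated it made at most 1 call. A list shifted by 0.5 was called in all 20 sets, and with no shift 0 lists were called. Because the genes were drawn independently, this does not show how often correlated genes would give false list calls. Moderated variances are already drawn toward a common value, so they differ less between probe sets than the unmoderated ones. The shares recovered may therefore be too high for the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.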

Results

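The transcriptome of rat tail tendon fibroblasts held in collagen gels was compared after 24 hours with the releasate of PRP or with that of PPP, which asks how the responses of these cells to the 2 products differ. The labels do not give the donors of the plasma, so a difference between donors, if they were not the same, is part of every value. There were 2 arrays per treatment and no untreated arrays among those analysed here, so every difference is between PRP and PPP and does not show which of them moved. Over the 14824 named probe sets the 2 PPP arrays correlated at r = 0.994 and the 2 PRP arrays at r = 0.995. Arrays of different treatments correlated at 0.987 to 0.990. These correlations are across probe sets, which are not independent replicates.

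Transcripts of several inflammatory mediators and of some matrix metalloproteinases were far higher with PRP than with PPP, and those of several tendon cell markers were lower. Cxcl1, a chemokine that attracts neutrophils, was 20.8-fold higher: its log2 level was 4.98 ± 0.04 with PPP and 9.36 ± 0.02 with PRP (SD, n = 2 each). Lcn2, a secreted protein that binds bacterial iron carriers, was 16.7-fold higher and Mmp3, the protease stromelysin-1, was 8.87-fold higher. Il1a, the cytokine interleukin 1 alpha, was 8.59-fold higher and Stc1, a secreted glycoprotein, was 7.83-fold higher. Prl6a1, a member of the prolactin family, was 8.83-fold higher. The largest falls were in Cilp, a matrix protein of cartilage and tendon (7.10-fold lower), Plekha6 (6.57-fold lower), C1qtnf3, a secreted protein related to complement C1q (6.39-fold lower), and Fmod, a proteoglycan that binds collagen fibrils (5.38-fold lower). Jag1, a ligand of Notch receptors, was 4.51-fold lower and Aoc3, a cell-surface amine oxidase, was 4.20-fold lower. The adjusted p of these 12 genes lay between 2.43e-04 and 0.00502 by limma.

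**Figure D1:**
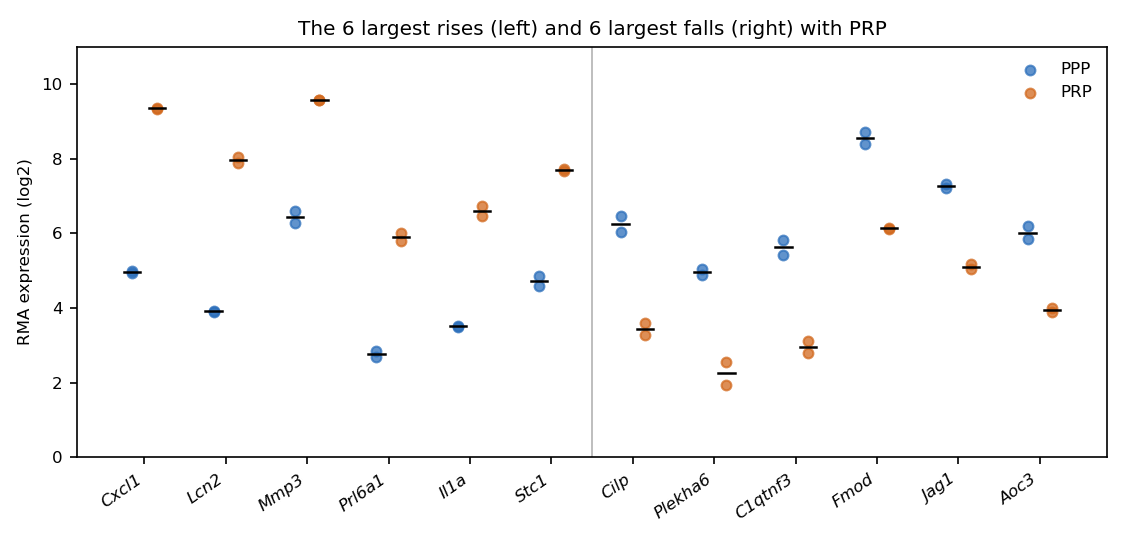
RMA expression on the log2 scale (vertical axis) of the 6 genes with the largest rise and the 6 with the largest fall with PRP; points are single arrays, 2 per treatment, and bars are group means. In each gene the arrays of one treatment lie apart from those of the other, which the rule that picked them required, from Cxcl1 (means 4.98 and 9.36) to Aoc3 (means 6.02 and 3.94).

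In all, 274 probe sets of 270 genes passed an adjusted p of 0.05 by limma: 123 probe sets were higher with PRP and 151 lower. That balance depended on the scaling, with 198 higher and 176 lower after the arrays were centred on their medians. Of the 274, 64 were more than 2-fold higher and 94 more than 2-fold lower. The smallest log2 difference among the calls was 0.64. The number of calls depended on the processing: an intensity trend in limma gave 808, of which 444 were higher, a replicate block gave 123, and a fit of all 36685 probe sets without a trend gave 2. With 1 array left out the calls fell to 56 without PPP replicate 1, 72 without PPP replicate 2, 81 without PRP replicate 1 and 67 without PRP replicate 2, and 0 of the 274 turned direction. In each of the 274 the 2 groups did not overlap, so leaving out 1 array could not turn its direction. The groups did not overlap in 46.4% of all probe sets tested either, where chance gives 33.3% for 2 against 2. The fits with 1 array left out had 1 residual degree of freedom. In them the log2 differences of the called genes named here stayed between 0.793 and 1.21 times those with all arrays. A call lost this way below therefore goes with a difference of similar size. A call already needs a gap between the arrays of a group that is small beside the difference. A ratio near 1 thus follows largely from the call and is no separate support for it. Cxcl1, Lcn2, Mmp3, Prl6a1, Il1a, Stc1, Cilp, C1qtnf3, Fmod, Jag1 and Aoc3 kept their calls whichever array was left out, while Plekha6 lost its call without either PPP array (highest adjusted p 0.0718).

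Transcripts of inflammatory cytokines and chemokines rose as a list, with a median log2 difference of 0.29 and an adjusted p of 2.52e-10 by limma's camera (adjusted p = 0.249 with an estimated correlation). Of 26 measured members, 8 rose, 0 fell and 18 did not pass (11 rose when adjusted over the list alone). Beside Cxcl1 and Il1a these were Ccl7, Ccl2, Cxcl16, Il6, Il33 and Ptgs2, the inducible cyclooxygenase. Ccl7, which draws monocytes, rose from 7.35 ± 0.05 to 9.31 ± 0.03 (SD, n = 2 each), and Ccl2, another monocyte chemokine, from 8.89 ± 0.02 to 10.61 ± 0.03. Il6 rose by 1.74 (SE 0.12) and Ptgs2 by 1.89 (SE 0.11) on the log2 scale, with adjusted p of 0.00368 and 0.00271 by limma. Several well-known cytokines did not pass: the log2 differences of Tnf, Il1b and Cxcl10 were -0.04, -0.09 and 0.11. Their levels were low, at 3.16, 2.69 and 4.07 with PPP and 3.13, 2.60 and 4.18 with PRP. Such levels could not be told from background, so the lack of a difference says little about these genes. Il33 lost its call without PPP replicate 1 or either PRP array (highest adjusted p 0.0817), and the other 7 kept theirs.

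The list of the NF-kB pathway and of genes induced by TNF also rose, with a median log2 difference of 0.38 and an adjusted p of 1.23e-07 by limma's camera (adjusted p = 0.334 with an estimated correlation). Of 24 measured members, 4 rose, 0 fell and 20 did not pass, and 10 rose when adjusted over the list alone. Tlr2, a receptor for bacterial lipoproteins, was 2.84-fold higher and Nfkbia, the NF-kB inhibitor that NF-kB itself induces, was 2.05-fold higher. Zc3h12a, an RNase that degrades cytokine messages, rose by 0.98 and Ripk2, a kinase of innate immune signalling, by 0.80 on the log2 scale. Nfkbia, Zc3h12a and Ripk2 lost their calls with any 1 array left out (adjusted p up to 0.0999, 0.117 and 0.191), and Tlr2 without either PPP array (up to 0.0877).

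Among 11 measured genes of complement and the acute phase, 3 rose and 8 did not pass (4 rose and 2 fell when adjusted over the list alone). The 3 were Lcn2, Ptx3, a soluble pattern-recognition protein (3.03-fold higher, adjusted p 0.00531 by limma), and C3, the central complement component, which rose by 1.71 on the log2 scale. The list passed limma's camera narrowly at an adjusted p of 0.0418 (adjusted p = 0.677 with an estimated correlation), and its call ended without PPP replicate 2 (0.172) or PRP replicate 1 (0.150), with arrays centred on their medians (0.0503) and with a replicate block (0.0768). C3 lost its call without either PPP array (adjusted p up to 0.0737).

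Tendon cell markers fell as a group, with a median log2 difference of -0.61 and an adjusted p of 3.28e-10 by limma's camera (adjusted p = 0.311 with an estimated correlation). Of 15 measured markers, 6 fell, 0 rose and 9 did not pass, and 11 fell when adjusted over the list alone. Fmod dropped from 8.56 ± 0.21 to 6.13 ± 0.02 and Cilp from 6.26 ± 0.29 to 3.43 ± 0.22 (SD, n = 2 each). Ogn, a small proteoglycan of connective tissue, fell by 1.46 on the log2 scale. Tnmd, a membrane protein characteristic of tendon, and Kera, the proteoglycan keratocan, each fell by 1.36. Their levels were low, at 4.46 and 3.82 with PPP and 3.11 and 2.46 with PRP, so these falls are uncertain to that extent. Egr2, a transcription factor of tendon development, fell by 1.05. Scx and Mkx, transcription factors of the tendon lineage, did not pass, with log2 differences of -0.55 and -0.55 and adjusted p of 0.139 and 0.187 by limma. The call of Egr2 was lost with any 1 array left out (adjusted p up to 0.212), and those of Tnmd and Kera without either PPP array or PRP replicate 2 (up to 0.0742 each).

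Collagens and other structural matrix genes were lower with PRP as a list (median log2 difference -0.38, adjusted p 1.59e-08 by limma's camera, adjusted p = 0.339 with an estimated correlation). Of 29 measured genes, 3 fell, 0 rose and 26 did not pass; adjusted over the list alone, 16 fell and 1 rose. The 3 were Fmod, which is also on the tendon list, Col11a1, a minor fibrillar collagen (2.55-fold lower, adjusted p 0.00717), and Postn, the matricellular protein periostin, which fell by 0.79 on the log2 scale. Col1a1 and Col1a2, the chains of type I collagen, had log2 differences of -0.66 and -0.53 (SE 0.12 and 0.11) and missed the threshold with adjusted p of 0.0650 and 0.104 by limma. Dcn, the proteoglycan decorin, had a positive difference of 0.56 and an adjusted p of 0.0709. Col11a1 lost its call without PPP replicate 1 or either PRP array (adjusted p up to 0.0656) and Postn with any 1 array left out (up to 0.208).

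Myofibroblast and contractile genes fell as a list, with a median log2 difference of -0.36 and an adjusted p of 1.93e-06 by limma's camera (adjusted p = 0.463 with an estimated correlation). Of 13 measured members, 3 fell, 0 rose and 10 did not pass, and 7 fell when adjusted over the list alone. Itga11, the alpha subunit of a collagen-binding integrin, was 3.88-fold lower and Actg2, a smooth muscle actin, was 3.04-fold lower, with adjusted p of 0.00293 and 0.00311 by limma. Lmod1, which nucleates actin filaments in smooth muscle, fell by 1.53 on the log2 scale and lost its call without PPP replicate 1 or either PRP array (adjusted p up to 0.0714).

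Matrix proteases and their inhibitors went both ways. Of 23 measured members 4 rose, 1 fell and 18 did not pass (6 rose and 2 fell when adjusted over the list alone). Mmp9, a gelatinase, rose to 5.55 on the log2 scale (adjusted p 0.00122 by limma) from 3.13, a low level not told apart from background. Its values on both PPP arrays were identical, as were those of 16 named probe sets in all. Mmp10 and Mmp13, a stromelysin and a collagenase, rose by 2.04 and 1.46. Timp3, a matrix-bound inhibitor of these enzymes, fell by 1.23. The list as a whole did not pass limma's camera (adjusted p 0.135), with a median of 0.01 and a mean of 0.32, though it passed without PRP replicate 2 (0.0395). Mmp13 lost its call without PPP replicate 1 or either PRP array (adjusted p up to 0.0723), and Timp3 without either PPP array or PRP replicate 2 (up to 0.215).

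Antioxidant and oxidative stress genes showed no common direction: 2 of 23 measured members rose, 2 fell and 19 did not pass, with 4 and 3 when adjusted over the list alone. Sod2, the mitochondrial superoxide dismutase, was 2.31-fold higher and Mt2A, a metallothionein, was 2.22-fold higher. Slc7a11, the cystine transporter, fell by 1.07 and Nqo1, a quinone reductase induced by Nrf2, by 0.70 on the log2 scale. Hmox1, heme oxygenase 1, had a difference of -0.32 that did not pass (adjusted p 0.375 by limma). The list's adjusted p was 0.840 by limma's camera. All 4 calls were lost with any 1 array left out, with adjusted p up to 0.0718 for Sod2, 0.0798 for Mt2A, 0.118 for Slc7a11 and 0.266 for Nqo1.

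Cell cycle genes were higher with PRP as a list. All 26 measured members had a positive difference, also after median centring or cyclic loess, from 0.12 to 0.73 with a median of 0.29 on the log2 scale, and limma's camera gave an adjusted p of 2.52e-10 (adjusted p = 0.249 with an estimated correlation). Only Mcm2, a subunit of the replicative helicase, passed by itself, at 1.66-fold (adjusted p 0.0411 by limma), and 7 rose when adjusted over the list alone. Mcm4, another subunit, was at 1.52-fold with an adjusted p of 0.0653. Mcm2 lost its call with any 1 array left out (adjusted p up to 0.254).

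Genes of cholesterol synthesis and uptake had a median log2 difference of 0.14, and 0 of 12 measured members passed, also over the list alone. Those with the smallest p were Hsd17b7 (log2 difference 0.50, SE 0.13) and Idi1 (0.41, SE 0.14), enzymes of sterol synthesis. The list's adjusted p was 0.0485 by limma's camera (adjusted p = 0.677 with an estimated correlation). That call ended without PPP replicate 2 (0.289), PRP replicate 1 (0.0709) or PRP replicate 2 (0.123), with dim probe sets left out (0.180), with median centring (0.0503), cyclic loess (0.205) or a replicate block (0.0590).

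Among growth factors and their receptors, 2 of 25 measured members rose, 1 fell and 22 did not pass (6 rose and 3 fell when adjusted over the list alone). Fgf10, a mesenchymal fibroblast growth factor, was 2.25-fold higher, Vegfc, a lymphatic growth factor, rose by 0.71 on the log2 scale, and Tgfb3 was 2.33-fold lower. Tgfb1 did not pass, with a log2 difference of -0.26. Fgf10 and Vegfc lost their calls with any 1 array left out (adjusted p up to 0.0750 and 0.259), and Tgfb3 without either PPP array or PRP replicate 2 (up to 0.0741). Of 15 measured genes of hypoxia and glycolysis, 1 rose, 2 fell and 12 did not pass (3 and 2 when adjusted over the list alone). Adm, the vasodilator peptide adrenomedullin, was 3.40-fold higher, whereas Ndrg1, a hypoxia-induced gene, was 2.94-fold lower and Car9, a carbonic anhydrase, fell by 0.82. Ndrg1 lost its call without PPP replicate 1 or PRP replicate 2 (adjusted p up to 0.0750) and Car9 with any 1 array left out (up to 0.254). The adjusted p of these 2 lists by limma's camera was 0.707 and 0.561.

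No autophagy gene passed over all probe sets: limma called 0 of 17 measured members at an adjusted p of 0.05, and 1 rose when adjusted over the list alone. The nearest were Wipi2, which acts in autophagosome formation (log2 difference 0.76, adjusted p 0.0693), and Tfeb, a transcription factor of lysosomal genes (log2 difference -0.45, adjusted p 0.159). The list's adjusted p was 0.946 by limma's camera. Of 19 measured interferon-stimulated genes, 1 rose and 18 did not pass, over the list alone as well. Usp18, a protease that removes ISG15, was 2.44-fold higher, while 16 members had negative differences (15 after median centring), among them Ifit3 at -0.45 (adjusted p 0.221), and the list did not pass (adjusted p 0.0910 by limma's camera). Usp18 lost its call with any 1 array left out (adjusted p up to 0.0845).

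**Figure D2:**
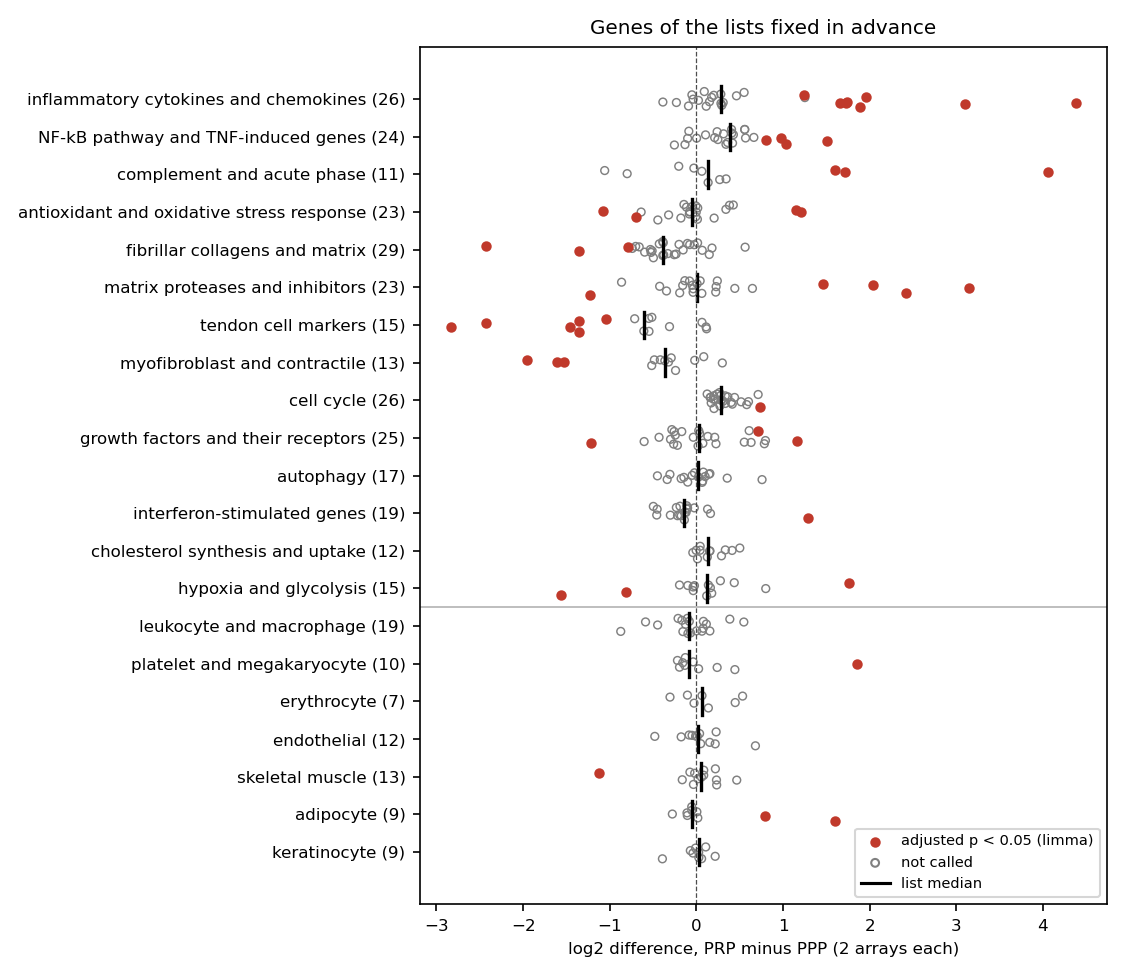
Log2 difference, PRP minus PPP (horizontal axis), of each measured gene in the 21 lists fixed in advance, with the number measured in brackets; filled points passed an adjusted p of 0.05, open points did not, bars mark list medians, and the horizontal line parts response lists from lists of other cell types. Called points lie to the right in the cytokine list (median 0.29) and to the left in the tendon list (median -0.61), while the 7 lists of other cell types have medians between -0.08 and 0.06.

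Markers of other cell types did not shift as groups: the adjusted p of the 7 lists by limma's camera ran from 0.561 to 0.910. Of 19 measured leukocyte and macrophage markers 0 passed over all probe sets, 1 rose and 2 fell over the list alone, and the smallest p was that of Tyrobp, a signalling adaptor of myeloid cells, whose difference was -0.87 (adjusted p 0.0559 by limma). Of 10 platelet and megakaryocyte markers Pf4, platelet factor 4, rose (3.61-fold, adjusted p 0.00398), while Ppbp, another platelet chemokine, and Gp9, a platelet glycoprotein, had differences of -0.16 and 0.03. Among 9 adipocyte markers Fabp4, a fatty acid binding protein, was 3.04-fold higher, and Lpl, lipoprotein lipase, rose by 0.79. Among 13 skeletal muscle markers Acta1, skeletal muscle actin, was 2.17-fold lower. No marker of red cells, endothelium or keratinocytes passed over all 7, 12 and 9 measured (limma, adjusted p of 0.05). Their smallest p values belonged to Hbb-b1, a beta globin (log2 difference 0.53), Tek, an endothelial receptor (0.68), and Krt17, a keratin (-0.39). Over the list alone, 1 platelet marker, 2 adipocyte markers, 1 muscle marker and 1 red cell marker passed. The platelet and adipocyte lists had medians below 0 (-0.08 and -0.05) with means above it (0.17 and 0.20) and an upward test, while the keratinocyte and muscle lists had medians above 0 (0.03 and 0.06), means below it (-0.01 and -5.82e-04) and an upward test. Fabp4 lost its call without either PPP array or PRP replicate 2 (adjusted p up to 0.0834), and Lpl and Acta1 with any 1 array left out (up to 0.257 and 0.237).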

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

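The tests of the platelet list and of the prolactin family and the fit of unnamed probe sets were chosen after the results they bear on had been seen, and the bound for leukocyte transcripts was written before. Probe sets that no single gene symbol names took no part in the comparisons above. When all 36685 probe sets were fitted with an intensity trend in limma, 34 of the 21861 without a single symbol passed an adjusted p of 0.05, 12 of them higher and 22 lower with PRP. The same limma fit without the trend called 0, with 2215 at an unadjusted p under 0.05. The largest rises were in probe sets 17882069 (log2 difference 2.53, SE 0.11) and 17784097 (2.30, SE 0.22). The largest falls were in 17881577 and 17881733, which hold identical values on every array (-1.96, SE 0.17), so the 34 stand for 33 distinct measurements.

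The rise of inflammatory genes with PRP was set against RNA carried over from blood cells in the releasate. Residual leukocytes would bring their abundant transcripts, but 9 of these (S100a8, S100a9, Lyz2, Tyrobp, Fcer1g, Ptprc, Itgb2, Lcp1 and Cd74) had a median log2 difference of -0.0667 (bootstrap 95% interval -0.45 to 0.16), below the bound of 0.5 set before, though they ran from -0.87 (Tyrobp) to 0.55 (Fcer1g, adjusted p 0.105), so Fcer1g alone lay above it. Residual platelets would raise the platelet list, whose 10 measured members had a median of -0.0818 (-0.16 to 0.24), with Pf4 as the exception; 3 of the 10, and 2 of the 19 leukocyte markers, lay above the median of all genes (4.11). The bootstrap intervals came from resampling genes, so they hold no spread between arrays. Neither median rose, whereas the 8 called cytokines rose by 1.25 to 4.38. Most of these markers were dim, however, and a low value could not be told from background. The medians therefore cannot decide whether blood-cell RNA was a source of those cytokines. A direct response of the fibroblasts to the releasate, or a rare cell type in the cultures, stays open too and was not tested.

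Of the prolactin family, best known from pituitary and placenta, 3 members were called: Prl6a1 rose by 3.14 (SE 0.13), Prl7a3 by 2.44 (SE 0.15) and Prl8a9 by 1.54 (SE 0.19) on the log2 scale. A single transcript read by the probe sets of the whole family would raise most of its 18 measured genes, but 3 of 18 were higher by more than 0.5, the same 3 that drew attention to the family. That count restates the observation, and the other 15, of which 12 were positive, had low values on all arrays, so it cannot be told from these data whether the 3 are separate transcripts. Probes shared among them stay open too, because no probe sequences were used. Prl6a1 and Prl7a3 kept their calls whichever array was left out, and Prl8a9 lost its call without either PPP array or PRP replicate 2 (adjusted p up to 0.163).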

How the results depend on the processing

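The 274 calls became 808 with an intensity trend in limma (444 higher, 364 lower), 650 with the dimmer probe sets left out (361 higher, 289 lower) and 488 at a threshold of 0.10. Only 2 remained, Cxcl1 and Lcn2, when all 36685 probe sets were fitted without a trend, where the prior degrees of freedom fell from 3.87 to 2.44 and the unnamed probe sets had a median residual SD of 0.166 against 0.120. All probe sets with a trend, chosen after seeing the data, gave 145. Leaving out 1 array gave 56 to 81 calls with 1 residual degree of freedom, the lone array being assumed to vary like the other group. Centring the arrays on their medians gave 374 (198 higher, 176 lower), cyclic loess 317 (125 higher, 192 lower; 267 of the 274 kept in the same direction, exact 95% interval 94.8% to 99.0%), robust moderation 261 and averaging probe sets of a gene 271. In no setting that kept the probe sets apart did any of the 274 turn direction, but only cyclic loess could have turned one. The 2 groups did not overlap in any of the 274, so leaving out 1 array could not. Median centring moved all log2 differences alike and by far less than the smallest called one, and the other settings left them unchanged. The replicate block, for numbers that share no stated animal or day and whose deviations correlated at 0.01, gave 123 calls, all among the 274. It left every log2 difference unchanged and 1 residual degree of freedom instead of 2. Calls were thus lost through precision and not through smaller differences. Of the 3 ways to split the 4 arrays into pairs 1, the real one, gave as many as 274 calls, and the highest other gave 0 by limma (298 and 378 at an unadjusted p under 0.05); 3 splits are too few for a share under 0.05.

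Of the 21 lists 8 passed limma's camera. With an estimated correlation 0 passed (3 at an unadjusted p under 0.05), and 6 to 9 did in all other settings of camera. The calls of complement and cholesterol were lost with median centring (adjusted p 0.0503 each) and with the replicate block (0.0768 and 0.0590); cholesterol was also lost with dim probe sets left out and with cyclic loess. The calls of both were also lost without some single arrays. The protease list passed without PRP replicate 2 (0.0395), and the interferon list at the threshold of 0.10 (0.0910). The fry test, which asks whether a list's genes moved, on balance, one way and does not compare them with other genes, called 8 lists, with proteases (0.0296) and without cholesterol (0.268), and is no repeat of camera. Of the 59 named genes that were called, 25 kept the call whichever array was left out. The replicate block ended 15 of these 59 calls, each of them also lost with some array left out, all probe sets with a trend ended 21 and all probe sets without one ended 57. No named gene or list reversed a call, though for called genes only cyclic loess could have reversed one.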

Other observations

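The tests in this part were chosen after seeing the data, except that the bounds for the ATF4 targets were written before their own differences had been looked at. By then the calls were known, and so were the summaries of the lists that hold Sesn2 and Ddit4, which are among these targets. Genes were grouped by the letters that open their symbols, and 236 such families with at least 8 measured genes were tested with limma's camera. At a preset correlation 7 passed an adjusted p of 0.05, and 0 did with an estimated correlation (adjusted p = 0.912 for each, 1 family at an unadjusted p under 0.05). Families higher with PRP were Mcm, subunits of the replicative helicase and its relatives (9 genes, median log2 difference 0.52), Nup, nucleoporins (16 genes, 0.22), Cep, centrosomal proteins (24 genes, 0.28), Ddx, RNA helicases (28 genes, 0.14), and Prl, the prolactin family (18 genes, 0.13). Lower were Itga, integrin alpha subunits (8 genes, -0.27), and Col, collagens (31 genes, -0.08). No family median changed sign after median centring or cyclic loess. Most of the Mcm family is also on the cell cycle list.

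Some of the called genes that fell with PRP are known targets of ATF4, a transcription factor of the amino acid and stress response. Trib3 fell by 1.76, Chac1 by 1.46, Slc7a11 by 1.07, Atf5 by 0.87 and Aldh1l2 by 0.78 on the log2 scale. Trib3 lost its call without PPP replicate 2 (adjusted p 0.0522), Chac1 without either PPP array or PRP replicate 2 (up to 0.0963), and Slc7a11, Atf5 and Aldh1l2 with any 1 array left out (up to 0.118, 0.205 and 0.198). The hypothesis that ATF4 targets are lower as a group was tested on 34 other genes that had not been used to find it, 33 targets and Atf4 itself. These genes were read on the same arrays as the 5 above, so they are no independent repeat of the comparison. All 24 of these that were measured had a negative difference, with a median of -0.35 (bootstrap 95% interval -0.44 to -0.25). The bootstrap resampled genes, so the interval holds no spread between arrays. By themselves 0 passed in limma (15 at an unadjusted p under 0.05). limma's camera gave an unadjusted p = 3.70e-11, or an unadjusted p = 0.0181 with an estimated correlation. In that last test the cytokine list had an unadjusted p of 0.0174, which became 0.249 when adjusted over the 21 lists. The transcript of Atf4 had a difference of -0.28 (adjusted p 0.341 by limma). Without Atf4, Sesn2 and Ddit4 all 21 were negative, with a median of -0.36 (-0.44 to -0.25). Their unadjusted p was 0.0204 by limma's camera with an estimated correlation. A shift of all genes at these intensities is argued against, since 0 of 10000 random lists matched on mean expression had a median as low and their central 95% ran from -0.06 to 0.14. The median was -0.32 after median centring (23 of 24 negative), -0.41 after cyclic loess and between -0.37 and -0.32 with 1 array left out. These values are consistent with less ATF4 activity under PRP than under PPP, or with more under PPP, and a difference in nutrients between the releasates may contribute, which was not tested.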
